A study of Arabidopsis thaliana with 18 samples.

How the data were processed

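Transcript levels were measured in seedling RNA of Arabidopsis Col-0 on 18 one-colour Agilent arrays (Cy3-labelled cRNA), 3 for each of 6 groups: DMSO, Ky-9 and Ky-72 without salt, and the same 3 with salt. The labels give a 24 h pretreatment at 1 µM, then 100 mM NaCl for 2 h in the salt groups, and 3 biological replicates per group. Groups and replicate numbers were taken from the sample labels. Groups without salt carry the label time 0 h and salt groups 2 h, so each salt comparison also spans those 2 h.

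The per-array files are scans read by Agilent Feature Extraction 10.7.3.1. Their gProcessedSignal is a linear intensity, background-subtracted, detrended spatially and multiplicatively, with low values replaced by a surrogate and with no normalization between arrays, per the file headers. The deposited value table holds log2 values of 52083 probes. These were normalized between arrays by the authors, as the columns share nearly all quantiles, and the values follow log2 gMedianSignal (r from 0.99755 to 0.99978). Per the submitters' processing notes RMA, limma and R 2.12.1 were used, without stated roles. The medians of the deposited log2 columns were 5.9112, 5.9062 and 5.9002 (DMSO), 5.9072, 5.8941 and 5.9102 (Ky-9), 5.8987, 5.8911 and 5.9057 (Ky-72), 5.8987, 5.9022 and 5.8982 (DMSO + salt), 5.8885, 5.8896 and 5.8949 (Ky-9 + salt) and 5.8865, 5.8896 and 5.8987 (Ky-72 + salt). Scale and direction follow from the match to the signal, while the background step and the exact method of centring stay unknown.

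Of 54778 spots per array 1319 were controls. Spots of one probe were averaged on the log2 scale after leaving out those marked as feature outliers (14 to 36 marked spots per array, 0 saturated). The 53459 remaining spots hold 52586 probes, 32878 of them named by one of 32781 loci. For 97 loci with several probes the one with the highest mean signal was used (median correlation across arrays within a locus 0.905, 8 under 0.5). A feature was tested if its probe was well above background on all 3 arrays of at least 1 group, which left 31726 of 52489 features. Probes without a locus name were tested as features but not named. Symbols came from the files and the reference table, which holds 32316 of the loci. The files name an older build than the reference, so no coordinates are given.

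The log2 of gProcessedSignal was reduced by each array's 75th percentile over non-control probes. The range of signal strength over the arrays is given in the report, and the median standard deviation between replicates of a group was 0.0843 to 0.119 on the log2 scale. One coefficient per group was fitted to all 18 arrays with limma 3.58.1 (lmFit and eBayes at default settings, 12 residual and 1.69 prior degrees of freedom) in R 4.3.3 with statmod 1.5.0, the data.table package (1.17.8) and MASS 7.3.60.0.1. P-values were adjusted by Benjamini and Hochberg over the tested features of a comparison, with a threshold of 0.05. The 11 comparisons were each compound against DMSO without and with salt, the compounds against each other without and with salt, salt in each of the 3 pretreatments, and the interaction of each compound with salt.

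Gene lists, comparisons, tests, the rule for named genes and the alternatives were set before the data were examined. The 19 lists hold 406 members, of which 383 were tested. They were tested with camera at its preset correlation of 0.01, and beside it with an estimated correlation and with fry, adjusted over the 19 lists of a comparison. A list's median, mean and counts of members past the test are given with its test. The rule for named genes took the 8 largest rises and falls with no overlap between arrays in the 5 main comparisons (each compound without and with salt, and salt in DMSO) and 5 each way in the other 6. From each list up to 4 members with the smallest adjusted p were added, and all histone deacetylase and ion transport members. Agreement of the compound effects was set against 20 simulated sets of unchanged groups sharing the same control arrays, and against the overlap that independence gives.

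Alternatives were quantile normalization, normexp background correction (offset 50), both together, no filter on dim probes, the deposited value table, the mean of probes per locus, slide as a random or fixed block, replicate number as a block, an intensity trend in the prior, the spread of the compared groups alone, a 2-fold threshold, and leaving out each array in turn. The array barcodes in the files place the samples on 3 slides: DMSO and Ky-9 on slide 1, Ky-72 replicate 1, DMSO + salt and Ky-9 + salt on slide 2, and Ky-72 replicates 2 and 3 and Ky-72 + salt on slide 3. With slide as a fixed block 5 of the 11 comparisons cannot be estimated. The random block took a correlation of 0.037 between arrays of one slide. It cannot remove a slide difference that coincides with group, so calls that stay under it do not speak against such a difference.

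The fits were tested on simulated data with 31726 genes, of which 67, 67 and 66 were changed by 0.5, 1 and 2 on the log2 scale. For Ky-9 against DMSO 43.3%, 77.6% and 90.9% were recovered with 8 unchanged genes called, and for Ky-72 against DMSO 40.3%, 82.1% and 83.3% with 2. The interaction with salt gave 34.3%, 70.1% and 92.4% with 7 for Ky-9, and 32.8%, 73.1% and 83.3% with 9 for Ky-72. For Ky-72 under salt with a simulated slide shift, 6931 unchanged genes were called without a slide term (64.2%, 85.1% and 100% recovered) and 5 with it (17.9%, 53.7% and 86.4%). That shift was drawn per gene with a standard deviation 2 times that between replicates. Its size was not taken from these slides, so the 6931 does not estimate false calls in these data. Of 19 simulated lists for Ky-9 against DMSO, 1 was shifted and called, and 0 others were called. The simulated genes varied independently of each other, so this does not test list calls where members vary together. The other comparisons were not tested in this way.

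Planned lists of transposable elements and ribosomal proteins, to be built by rule from gene descriptions (2 lists), were not built, as neither the files nor the reference table hold descriptions. Histone acetylation was not analysed here.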

Results

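The series held 18 one-colour Agilent arrays of 5-day-old Arabidopsis Col-0 seedlings in 6 groups of 3 biological replicates. Seedlings had been kept for 24 h with 1 µM Ky-9, 1 µM Ky-72 or DMSO and were then sampled without salt or after 2 h in 100 mM NaCl. The comparisons asked what each histone deacetylase inhibitor did to transcript levels without stress, what salt did without and with inhibitor, what each inhibitor did under salt, and where Ky-9 and Ky-72 differed. Between 55.6% and 62.7% of spots on an array were well above background, and the 75th percentile of the processed signal ran from 558.4 (DMSO + salt replicate 3) to 1091.6 (DMSO replicate 1). After scaling, replicates of a group correlated across genes at 0.991 to 0.995 (genes are not independent replicates), and 31726 features were tested, 23137 of them named by a locus.

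Changes are log2 differences ± standard error with n = 3 arrays per group, and adjusted p-values are from limma over all tested features of a comparison. As the labels state biological replicates, these p-values measure the spread between such replicates. For each gene named as changed between a pair of groups, the 3 arrays of one group all lay beyond the 3 of the other, which chance gives in 10% of cases for any one gene. Where no array of a group measured a gene well above background, a lower bound is given as "at least N-fold". It sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. It allows for dim signal only and leaves out the spread between replicates, so a 95% interval can reach lower. With salt in DMSO, for example, RRTF1 was at least 119-fold higher, at log2 6.98 with a 95% interval of 4.97 to 8.98.

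The first component of all tested features held 53.8% of the variance and separated salt (-87.15 to -53.52) from no salt (54.08 to 97.82). The second, with 15.4%, separated the DMSO groups (43.66 to 60.61) from all 4 compound groups (-42.72 to -11.7).

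**Figure D1:**
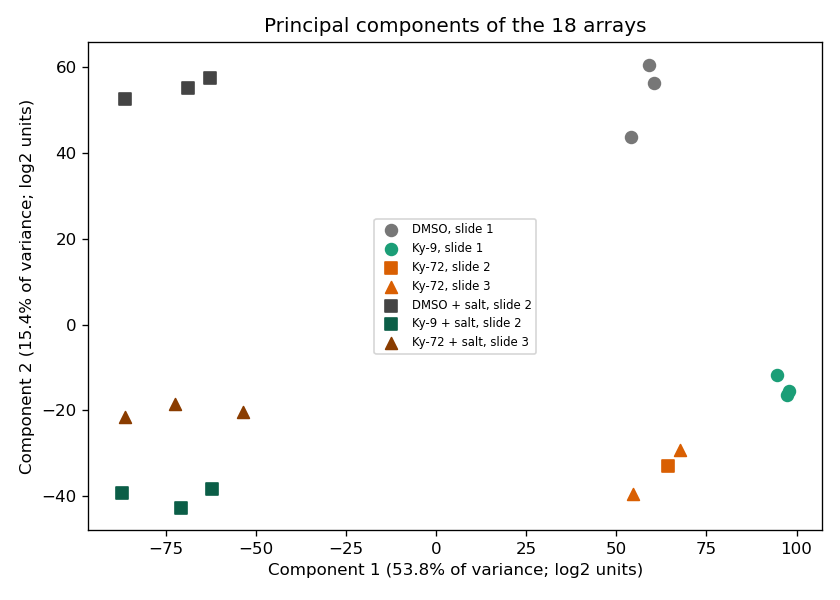
Positions of the 18 arrays on the first and second principal component (log2 units), coloured by group and shaped by slide. Salt lies along component 1 (53.8% of the variance) and compound against DMSO along component 2 (15.4%), and group and slide largely coincide.

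Ky-9 without salt was compared with DMSO first. The largest rises were in SRO4 (log2 8.12 ± 0.46, adjusted p = 1.2e-08, well above background on 2 of 3 DMSO arrays), AT2G17850 (7.84 ± 0.36, adjusted p = 1.6e-09), AT5G10040 (7.02 ± 0.52, adjusted p = 1.4e-07), AT3G01345 (7.01 ± 0.15, adjusted p = 3.5e-12) and AT2G14247 (6.78 ± 0.28, adjusted p = 6.2e-10). AT2G29870 rose by 6.61 ± 0.58, AT1G33030 at least 13.9-fold, and the plant cysteine oxidase gene PCO2 (AT5G39890) by 5.50 ± 0.36 (adjusted p = 4.1e-08). Large falls among genes measured in both groups were in the kinase gene CIPK20 (-5.55 ± 0.17, adjusted p = 4.6e-11), MLP328 (-5.26 ± 0.26, adjusted p = 3.4e-09) and the abscisic acid 8'-hydroxylase gene CYP707A2 (-4.55 ± 0.13, adjusted p = 3.2e-11). Also low were AT5G35935 (at least 7.77-fold), the myrosinase-binding protein gene MBP2 (at least 7.81-fold) and CYP710A4 (at least 8.78-fold). AT2G37030 fell by 4.72 on the log2 scale (standard error 0.82) and was measured on 1 of 3 Ky-9 arrays.

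Flavonoid and anthocyanin synthesis genes rose with Ky-9: of 22 measured members 17 rose, 3 fell and 2 did not pass the test, with the same counts of rises and falls adjusted over the list alone (median 1.36, adjusted p = 2.6e-07, and adjusted p = 0.38 with an estimated correlation). They included PAL1, the entry enzyme of phenylpropanoid synthesis (1.49 ± 0.07, adjusted p = 1.2e-09), FLS1 (1.78 ± 0.08, adjusted p = 1.6e-09), F3H (1.91 ± 0.11, adjusted p = 1e-08) and UGT78D2 (1.39 ± 0.09, adjusted p = 2.5e-08). Of 22 xenobiotic detoxification genes 18 rose and 1 fell, with equal counts adjusted over the list alone (median 1.05, adjusted p = 1.6e-06, and adjusted p = 0.32 with an estimated correlation). Among them the glutathione transferase genes GSTU24 and GSTU25 rose by 3.19 ± 0.13 (adjusted p = 5.6e-10) and 2.52 ± 0.09 (adjusted p = 1.7e-10).

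Chaperone genes rose as well: 10 of 19 heat shock list members rose and 1 fell, also when adjusted over the list alone (median 0.76, adjusted p = 0.0018, and adjusted p = 0.38 with an estimated correlation). The heat shock factor gene HSFA2 rose by 4.48 ± 0.22 (adjusted p = 2.5e-09), HSP70 by 3.86 ± 0.15 (adjusted p = 4.1e-10), HSP90.1 by 3.73 ± 0.11 (adjusted p = 3.2e-11) and HSP101 by 2.81 ± 0.14 (adjusted p = 3e-09). Root-abundant genes had 11 rises and 0 falls among 15, and the same counts adjusted over the list alone (median 0.55, adjusted p = 0.0018, and adjusted p = 0.38 with an estimated correlation). The expansin gene EXPA7 was at 1.04 ± 0.13 (adjusted p = 2e-05) and the nitrate transporter gene NRT2.1 at 1.46 ± 0.19 (adjusted p = 2.5e-05).

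In the other direction, 16 of 29 cell cycle genes fell and 4 rose, equally adjusted over the list alone (median -0.26, adjusted p = 0.014, and adjusted p = 0.39 with an estimated correlation). CYCA3;1 changed by -0.61 ± 0.06 (adjusted p = 2.4e-06). Of 25 rapid stress transcription factor genes 12 fell and 1 rose, or 13 and 1 adjusted over the list alone (median -0.99, adjusted p = 0.018, and adjusted p = 0.66 with an estimated correlation). ZAT10 was at -3.12 ± 0.42 (adjusted p = 3.4e-05) and ERF2 at -3.08 ± 0.52 (adjusted p = 0.00024). Photosynthesis genes had 11 falls and 3 rises among 22, also adjusted over the list alone (median -0.18, adjusted p = 0.042, and adjusted p = 0.39 with an estimated correlation). One of them was LHCB4.1 (-0.53 ± 0.06, adjusted p = 4.2e-06). The photosynthesis list call was lost with replicate number as a block.

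Transcripts of the histone deacetylase family itself moved little as a list: 8 of 17 members rose, 3 fell and 6 did not pass, or 8 and 4 adjusted over the list alone (median 0.14, adjusted p = 0.15). HDA18 fell by 1.71 on the log2 scale (standard error 0.11, adjusted p = 3.8e-08) and HDA14 by 0.66 (standard error 0.07, adjusted p = 2.5e-06). HDA9 (0.60 ± 0.05, adjusted p = 2.6e-07), HDA6 (0.50 ± 0.04, adjusted p = 6.2e-07) and HDT3 (0.55 ± 0.05, adjusted p = 1.1e-06) rose. Ion transport genes were split between 7 rises and 8 falls among 24 (7 and 10 adjusted over the list alone, median -0.00). The potassium channel gene AKT2 fell by 1.78 on the log2 scale (standard error 0.10, adjusted p = 1e-08), SOS3 changed by -0.80 ± 0.11 (adjusted p = 4.8e-05). The sodium/proton antiporter gene SOS1 rose by 0.34 ± 0.07 (adjusted p = 0.0011). For the sodium transporter gene HKT1 the 95% interval of the change was -0.25 to 0.52.

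Single members of other lists also moved. The clock-associated genes CDF1 (-2.15 ± 0.09, adjusted p = 6.2e-10) and ELF4 (1.51 ± 0.09, adjusted p = 1.5e-08) went opposite ways within a list of 8 rises and 8 falls among 24. The jasmonate-responsive VSP1 fell at least 10.2-fold while JAZ3 rose by 1.74 ± 0.18 (adjusted p = 2.7e-06). The floral repressor genes SVP (-1.07 ± 0.08, adjusted p = 1.4e-07) and FLC (-0.86 ± 0.11, adjusted p = 2.1e-05) fell, and the 12S globulin gene CRU3 fell at least 8.47-fold. The kinase gene OST1 rose by 1.26 ± 0.09 (adjusted p = 7.1e-08), and the orphan gene QQS fell (-1.68 ± 0.22, adjusted p = 2.9e-05).

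With Ky-9, 15101 of 31726 features passed the test, 7608 higher and 7493 lower (50.4% higher, or 62.5% under normexp background correction, 46.5% under quantile normalization and 46.6% in the value table). At least a 2-fold change was met by 2630 (1118 higher, 1512 lower). All 6 arrays lay on slide 1, so each value is also a within-slide value. Slide as a block leaves these estimates as they were and changes only the spread. With slide as a block 15218 features passed and the 7 list calls stayed (flavonoid 5.5e-07, xenobiotic 2.2e-06, heat shock 0.0023, root 0.0023, cell cycle 0.015, rapid factors 0.02, photosynthesis 0.048 as adjusted p).

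**Figure D2:**
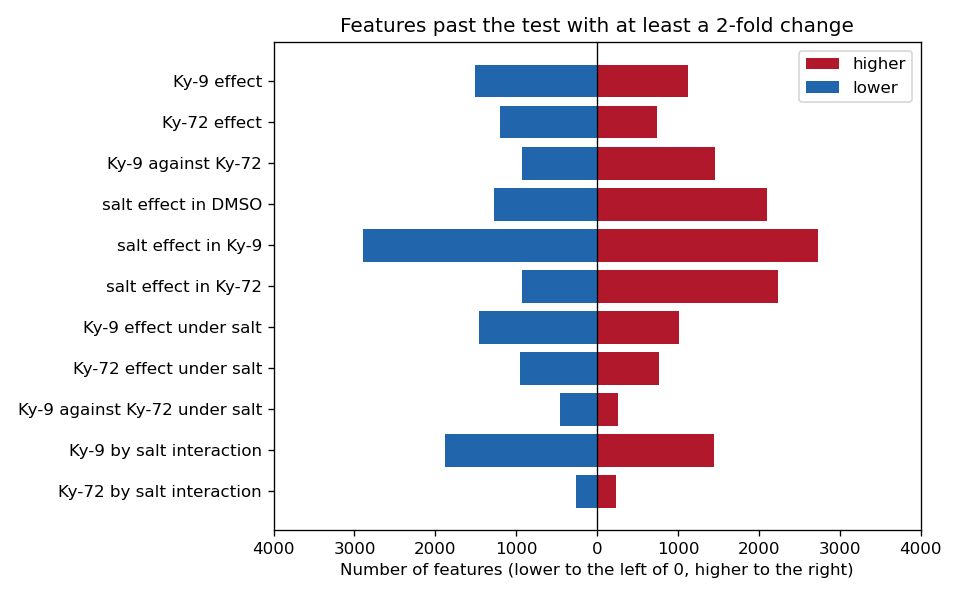
Number of features past the test with at least a 2-fold change in each of the 11 comparisons, lower to the left of 0 and higher to the right. Salt in Ky-9 had 5618 such features and the Ky-72 by salt interaction 500.

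Ky-72 without salt was compared with the same DMSO arrays. Several of the largest rises were in genes named above: AT3G01345 (6.82 ± 0.15, adjusted p = 5e-12), SRO4 (4.90 ± 0.46, adjusted p = 4.2e-06, 2 of 3 DMSO arrays measured), AT5G10040 (4.68 ± 0.52, adjusted p = 1.3e-05), AT2G29870 (4.50 ± 0.58, adjusted p = 4.6e-05), AT2G17850 (4.33 ± 0.36, adjusted p = 1.3e-06) and AT2G14247 (3.99 ± 0.28, adjusted p = 3.8e-07). AT1G16620 rose by 4.85 ± 0.20 (adjusted p = 6.9e-09) and AT3G29120 at least 7.12-fold. The seed storage genes CRU3 (at least 8.62-fold) and SESA2, a 2S albumin gene (at least 4.28-fold), stood among the largest falls. SESA4 of the same list rose (0.86 ± 0.18, adjusted p = 0.0021), and the seed list as a whole was not called. The expansin gene EXPA2 fell at least 11.6-fold, AT5G35935 at least 7.9-fold and AT2G41415 at least 4.09-fold. AT2G41810 changed by -3.91 ± 0.25 (adjusted p = 1.7e-07). AT5G55410 changed by -4.30 ± 0.65 (adjusted p = 0.00015) and was measured on 1 of 3 Ky-72 arrays.

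Of the 22 flavonoid genes 15 rose and 1 fell with Ky-72, or 15 and 2 adjusted over the list alone (median 0.79, adjusted p = 1.3e-06, and adjusted p = 0.73 with an estimated correlation). The anthocyanin pathway genes UGT75C1 (2.05 ± 0.14, adjusted p = 2.9e-07), UF3GT (1.98 ± 0.14, adjusted p = 4.8e-07) and LDOX (1.71 ± 0.12, adjusted p = 4.7e-07) were among them. Xenobiotic detoxification genes had 11 rises and 0 falls among 22, also adjusted over the list alone (median 0.78, adjusted p = 1.1e-05, and adjusted p = 0.45 with an estimated correlation). GSTU24 rose by 2.49 ± 0.13 (adjusted p = 3.9e-08) and GSTU25 by 2.18 ± 0.09 (adjusted p = 6.9e-09). Auxin response genes had 0 rises and 10 falls among 25, or 9 falls adjusted over the list alone (median -0.49, adjusted p = 0.024, and adjusted p = 0.77 with an estimated correlation). Falls included SAUR-AC1 (-1.30 ± 0.18) and the auxin synthesis gene TAA1 (-0.61 ± 0.07, adjusted p = 2.3e-05).

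Among 17 histone deacetylase genes 8 rose and 3 fell, also adjusted over the list alone (median 0.08, adjusted p = 0.14). HDT3 (0.48 ± 0.05, adjusted p = 8.6e-06) and HDA6 (0.39 ± 0.04, adjusted p = 1.5e-05) rose. HDA18 fell (-0.62 ± 0.11, adjusted p = 0.00054). The kinase gene SOS2 fell by 0.55 on the log2 scale (standard error 0.05, adjusted p = 4.4e-06). The potassium channel gene SKOR rose by 1.14 ± 0.16 (adjusted p = 9.4e-05), and AKT2 lay between -0.30 and 0.13. The defence marker gene PR1 rose by 3.93 ± 0.43 (adjusted p = 1.3e-05). Of 19 heat shock genes 9 rose and 2 fell without a list call (median 0.25, adjusted p = 0.079), HSP70 by 1.52 ± 0.15 (adjusted p = 6.8e-06) and HSP90.1 by 1.15 ± 0.11 (adjusted p = 3e-06). HSFA3 fell (-1.13 ± 0.14). The late embryogenesis gene LEA4-5 rose by 1.37 ± 0.21 (adjusted p = 0.00015) and COR15B fell (-1.77 ± 0.34, adjusted p = 0.00088).

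In all 13921 features passed, 6546 higher and 7375 lower (47% higher, 57.2% under normexp), and 1939 met a 2-fold change (744 higher, 1195 lower). Among features with a locus 5515 were higher and 5014 lower. DMSO lay on slide 1 and Ky-72 on slides 2 and 3, so slide and group cannot be told apart. With slide as a random block 13208 features passed and the flavonoid, xenobiotic and auxin calls stayed (adjusted p = 9.8e-07, 1.1e-05 and 0.024). That block, with a correlation of 0.037 between arrays of one slide, cannot remove a slide difference that coincides with group.

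**Figure D3:**
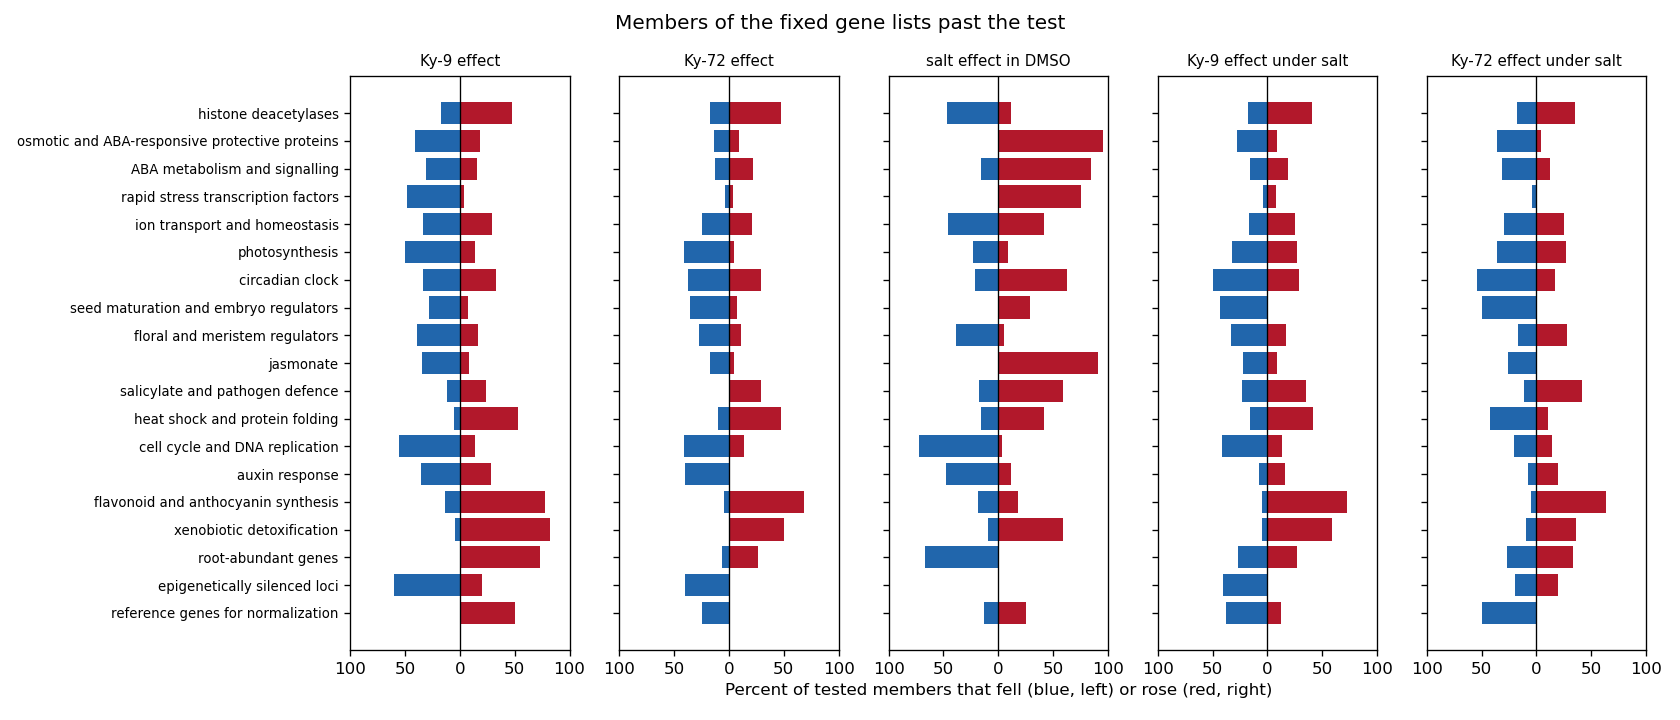
Percent of tested members of each fixed list that rose (right) or fell (left) past the test in the 5 main comparisons. Flavonoid genes rose in 17 of 22 cases with Ky-9 and 15 of 22 with Ky-72, and osmotic protective genes in 21 of 22 with salt in DMSO.

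The compounds were given at the same dose and time, and were compared directly. Ky-9 exceeded Ky-72 in AT4G32630 (at least 7.4-fold), the auxin repressor gene IAA15 (at least 5.82-fold), AT2G17850 (3.51 ± 0.36, adjusted p = 7e-06) and the iron-regulated bHLH38 (3.41 ± 0.59, adjusted p = 0.0004, 2 of 3 Ky-72 arrays measured) and BHLH100 (3.44 ± 0.61, adjusted p = 0.00052, 1 of 3). Ky-72 exceeded Ky-9 in AT4G33720 (-5.25 ± 0.49, adjusted p = 3.2e-06), CYP707A2 (-4.29 ± 0.13, adjusted p = 4e-10), AT5G52670 (at least 6.74-fold) and CYP710A4 (at least 4.91-fold).

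Heat shock genes were higher with Ky-9 in 8 of 19 cases and lower in 2 (median 0.60, adjusted p = 0.018, and adjusted p = 0.65 with an estimated correlation). Among them were HSFA2 (3.32 ± 0.22, adjusted p = 1.5e-07), HSP101 (2.58 ± 0.14, adjusted p = 3.1e-08), HSP90.1 (2.57 ± 0.11, adjusted p = 4.5e-09) and HSP70 (2.34 ± 0.15, adjusted p = 1.6e-07). Root-abundant genes were higher in 9 and lower in 0 of 15 (median 0.29, adjusted p = 0.01, and adjusted p = 0.65 with an estimated correlation). Examples were PRP3 (1.77 ± 0.15, adjusted p = 1.4e-06) and EXPA7 (1.37 ± 0.13, adjusted p = 4e-06). Rapid stress transcription factors were lower with Ky-9 in 10 and higher in 0 of 25 (median -0.72, adjusted p = 0.01, and adjusted p = 0.65 with an estimated correlation). ZAT10 changed by -2.96 ± 0.42 and ERF2 by -2.85 ± 0.52.

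A further 3 lists passed near the threshold, each at adjusted p = 0.043 and at adjusted p = 0.65 with an estimated correlation: abscisic acid genes (3 higher and 11 lower of 32, median -0.17), salicylate genes (1 and 5 of 17, median -0.61) and reference genes (6 and 0 of 8, median 0.18). All 3 calls were lost under quantile normalization, normexp and the deposited value table. Single genes that differed were AKT2 (-1.70 ± 0.10, adjusted p = 7.1e-08), the cation/proton exchanger gene CHX17 (1.14 ± 0.14), CDF1 (-1.52 ± 0.09, adjusted p = 7.1e-08), SVP (-1.20 ± 0.08, adjusted p = 1.8e-07), PR1 (-1.90 ± 0.43, adjusted p = 0.003) and HDA18 (-1.09 ± 0.11, adjusted p = 6.4e-06).

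No difference passed for HDT3 (0.07, interval -0.04 to 0.18), SRT1 (-0.01, -0.19 to 0.17), SOS1 (-0.03, -0.18 to 0.12), AHA1 (0.03, -0.08 to 0.15), AKT1 (0.04, -0.08 to 0.16) or NHX2 (0.07, -0.09 to 0.23). Together 14494 features differed, 7855 higher with Ky-9 and 6639 lower, and 2396 by at least 2-fold (1463 and 933). The balance turned under quantile normalization (54.2% higher to 47.3%), in the value table (47.9%) and among features with a locus (5155 and 5444, at 2-fold 496 and 577). Slide and compound cannot be told apart here, and with slide as a random block 13843 passed and the 6 list calls stayed.

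Across genes, which are not independent replicates, the Ky-9 and Ky-72 effects without salt correlated at r = 0.557 (rho 0.469), with a covariance of 0.205. Simulated unchanged groups sharing the same 3 DMSO arrays gave r = 0.498 and a covariance of 0.0239, a difference in covariance of 0.181. The sign was the same in 67.4% of features against 66.7% in the simulated groups. Both compounds raised 3796 features where independence gives 1570 and lowered 3809 where it gives 1742, while 844 went opposite ways. At 2-fold the overlaps were 386 against 26.2 and 459 against 57. As 3 control arrays cannot be split into sets of 2 per compound, part of the excess may come from the shared controls. The r of 0.498 in unchanged groups does not give the size of that part. In the simulation its covariance was 0.0239, against the 0.205 measured.

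Salt in DMSO-treated seedlings was examined next. The cold-response regulator gene CBF1 rose at least 113-fold, RRTF1 at least 119-fold, AT2G32130 at least 55.7-fold, MYB102 at least 53.5-fold, BHLH92 at least 50.6-fold, DIP2 at least 41.5-fold and AT1G22810 at least 39.1-fold. The heat shock factor gene HSFA6B rose by 7.64 ± 0.40 (adjusted p = 8.3e-09). Among the large falls were AT2G37030 (at least 25.7-fold), SOB5 (-5.02 ± 0.47, adjusted p = 1.4e-06, 2 of 3 salt arrays measured), AT4G10265 (-4.96 ± 0.27, adjusted p = 1.1e-08), AT4G10270 (-4.45 ± 0.27, adjusted p = 2.8e-08), the abscisic acid receptor gene PYL6 (-4.42 ± 0.23, adjusted p = 7e-09) and AT1G70270 (-4.04 ± 0.26, adjusted p = 5.3e-08).

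Of 22 osmotic protective genes 21 rose and 0 fell, also adjusted over the list alone (median 2.15, adjusted p = 2.7e-15, and adjusted p = 0.13 with an estimated correlation). LEA4-5 was at 6.64 ± 0.21 (adjusted p = 8e-10), RD29B at 4.76 ± 0.27 (adjusted p = 1.4e-08) and XERO2 at 3.90 ± 0.17 (adjusted p = 1.9e-09). Abscisic acid genes had 27 rises and 5 falls among 32 (median 1.83, adjusted p = 1.2e-11, and adjusted p = 0.059 with an estimated correlation). The synthesis gene NCED3 (5.05 ± 0.23, adjusted p = 2.7e-09) and the phosphatase gene HAI1 (6.07 ± 0.28, adjusted p = 2.5e-09) rose, while the receptor gene PYL5 fell (-2.56 ± 0.10, adjusted p = 1.1e-09). Of 25 rapid stress transcription factors 19 rose and 0 fell (median 1.5, adjusted p = 1.6e-07, and adjusted p = 0.38 with an estimated correlation). CBF3 rose by 5.65 ± 0.27 (adjusted p = 4.2e-09).

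Jasmonate genes had 21 rises and 0 falls among 23, or 22 rises adjusted over the list alone (median 1.5, adjusted p = 5.6e-09, and adjusted p = 0.38 with an estimated correlation). TAT3 rose by 4.57 ± 0.45 (adjusted p = 1.9e-06). Clock genes rose in 15 and fell in 5 of 24 cases (median 0.60, adjusted p = 8.5e-05, and adjusted p = 0.015 with an estimated correlation). PRR5 rose by 2.58 ± 0.13 (adjusted p = 6.9e-09). Xenobiotic genes had 13 rises and 2 falls among 22 (median 0.50, adjusted p = 0.0001, and adjusted p = 0.19 with an estimated correlation). Salicylate genes had 10 and 3 of 17 (median 0.87, adjusted p = 0.012, and adjusted p = 0.38 with an estimated correlation). Seed genes had 4 and 0 of 14 (median 0.86, adjusted p = 0.012, and adjusted p = 0.43 with an estimated correlation). EM6 rose at least 16.3-fold.

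Cell cycle genes fell in 21 and rose in 1 of 29 cases, or 22 and 1 adjusted over the list alone (median -0.27, adjusted p = 3.7e-05, and adjusted p = 0.19 with an estimated correlation). The replication gene MCM2 changed by -0.65 ± 0.06 (adjusted p = 5.7e-07). Root-abundant genes had 0 rises and 10 falls among 15 (median -0.41, adjusted p = 0.012, and adjusted p = 0.38 with an estimated correlation). PRP1 changed by -1.21 ± 0.16. Ion transport genes had 10 rises and 11 falls among 24, with a median of -0.08, a mean of 0.08 and a test direction of up (adjusted p = 0.41). NHX2 (1.22 ± 0.07, adjusted p = 3e-08), SOS3 (1.13 ± 0.11), HAK5 (2.53 ± 0.39) and SOS1 (0.27 ± 0.07) rose. CAX1 (-1.50 ± 0.10, adjusted p = 5e-08) and HKT1 (-1.24 ± 0.18, adjusted p = 6.1e-05) fell, and SOS2 lay between -0.18 and 0.05. Histone deacetylase genes rose in 2 and fell in 8 of 17 cases (median -0.19, adjusted p = 0.4). HDT1 was at -0.49 ± 0.07 (adjusted p = 3.6e-05), HDA2 at 0.65 ± 0.10 (adjusted p = 0.00013) and HDA6 between -0.08 and 0.10. Reference genes moved too: ACT2 fell (-0.72 ± 0.05, adjusted p = 9.8e-08) and UBQ10 rose (0.75 ± 0.07, adjusted p = 1e-06).

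Salt changed 15663 features, 6276 higher and 9387 lower (40.1% higher, 59.2% under normexp), and 3376 by at least 2-fold (2100 higher, 1276 lower). DMSO lay on slide 1 and DMSO + salt on slide 2, so slide and salt cannot be told apart, nor can salt and the 2 h that passed. With slide as a random block 14894 features passed and the 10 list calls stayed.

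Salt was compared without salt in Ky-9-treated seedlings too, relative to a median shift of -0.11 on the log2 scale over all features. FAMT rose by 10.34 ± 0.89 (adjusted p = 3e-07, 1 of 3 Ky-9 arrays measured), AT3G44870 at least 190-fold, RRTF1 at least 208-fold, AT1G70130 at least 133-fold and TAT3 by 8.73 ± 0.45 (adjusted p = 2.1e-09, 2 of 3). Genes that Ky-9 had raised stood first among the falls: SRO4 (at least 402-fold), AT2G17850 (-8.84 ± 0.36, adjusted p = 3e-10), AT5G10040 (-7.78 ± 0.52, adjusted p = 2.4e-08), PCO2 (-7.59 ± 0.36, adjusted p = 1e-09) and AT2G14247 (-7.32 ± 0.28, adjusted p = 2.1e-10).

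In these seedlings 21 of 22 osmotic protective genes rose and 1 fell (median 2.19, adjusted p = 1.7e-11, and adjusted p = 0.27 with an estimated correlation). RD29B rose by 6.45 ± 0.27 (adjusted p = 3.1e-10) and LEA4-5 by 5.36 ± 0.21 (adjusted p = 2.1e-10). Abscisic acid genes had 26 rises and 5 falls of 32 (median 1.93, adjusted p = 1e-10, and adjusted p = 0.13 with an estimated correlation). Rapid factors had 24 and 0 of 25 (median 3.09, adjusted p = 1.7e-11, and adjusted p = 0.41 with an estimated correlation). Jasmonate genes had 19 and 1 of 23 (median 2.00, adjusted p = 2.1e-07, and adjusted p = 0.41 with an estimated correlation). CYP707A2 rose by 4.39 ± 0.13 (adjusted p = 4.9e-11), ZAT10 by 5.47 ± 0.42 (adjusted p = 9.4e-08) and AKT2 by 2.31 ± 0.10 (adjusted p = 4.8e-10). HSP90.1 fell by 3.00 on the log2 scale (standard error 0.11, adjusted p = 1.3e-10) and PRP3 by 2.31 (standard error 0.15, adjusted p = 1.9e-08). Also called were salicylate (10 and 1 of 17, median 0.77, adjusted p = 0.0076, and adjusted p = 0.41 with an estimated correlation). Further calls were clock (10 and 5 of 24, median 0.24, adjusted p = 0.018, and adjusted p = 0.13 with an estimated correlation). So were root (3 and 11 of 15, median -0.75, adjusted p = 0.014, and adjusted p = 0.41 with an estimated correlation) and cell cycle genes (1 and 14 of 29, median -0.13, adjusted p = 0.046, and adjusted p = 0.44 with an estimated correlation). The cell cycle call was lost under quantile normalization, normexp and the value table. Of 20033 features past the test 7838 were higher and 12195 lower, with 5618 at 2-fold (2729 and 2889, or 1881 and 1490 among features with a locus). Slide and salt cannot be told apart, and a random slide block left 19421.

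With Ky-72, salt raised AT1G70130 (at least 105-fold), CBF1 (at least 82.4-fold), RRTF1 (at least 112-fold), BHLH92 (at least 53.4-fold) and HSFA6B (7.54 ± 0.40, adjusted p = 1.4e-08, 2 of 3 Ky-72 arrays measured). It lowered AT4G10265 (-7.74 ± 0.27, adjusted p = 6.2e-10), AT4G10270 (-7.02 ± 0.27, adjusted p = 1.5e-09), the regulator genes LBD41 (-6.85 ± 0.29, adjusted p = 2e-09) and HRA1 (AT3G10040, -6.16 ± 0.26, adjusted p = 2e-09), and AT1G33055 (at least 16.2-fold). Osmotic genes rose in 20 and fell in 0 of 22 cases, or 21 rises adjusted over the list alone (median 1.81, adjusted p = 1.2e-13, and adjusted p = 0.17 with an estimated correlation). LEA4-5 rose by 4.65 ± 0.21 (adjusted p = 3.4e-09). Abscisic acid genes had 25 rises and 6 falls of 32 (median 1.98, adjusted p = 6.7e-11, and adjusted p = 0.073 with an estimated correlation). NCED3 rose by 4.94 ± 0.23 (adjusted p = 4.7e-09). Rapid factors had 22 and 0 of 25 (median 1.92, adjusted p = 2.1e-10, and adjusted p = 0.48 with an estimated correlation). Jasmonate genes had 20 and 0 of 23 (median 1.46, adjusted p = 1.4e-08, and adjusted p = 0.48 with an estimated correlation).

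Smaller list calls with Ky-72 were clock (14 and 5 of 24, median 0.26, adjusted p = 0.0083, and adjusted p = 0.073 with an estimated correlation), salicylate (7 and 2 of 17, median 0.38, adjusted p = 0.026), cell cycle (0 and 14 of 29, median -0.17, adjusted p = 0.024) and root genes (2 and 11 of 15, median -0.60, adjusted p = 0.027), the last 3 at adjusted p = 0.48 with an estimated correlation. HSP90.1 fell by 1.59 on the log2 scale (standard error 0.11, adjusted p = 7.6e-08). PRR5 rose by 2.85 ± 0.13 (adjusted p = 4.6e-09) and NHX2 by 0.94 ± 0.07 (adjusted p = 3.7e-07). The test passed 15324 features, 6009 higher and 9315 lower, and 3165 at 2-fold (2233 and 932). Within slide 3, which held 5 of the 6 arrays, the value is that of slide as a fixed block: 13975 features and all 8 list calls, with a heat shock call added (median -0.97, adjusted p = 0.044).

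Ky-9 was compared with DMSO under salt. AT3G01345 (7.19 ± 0.15, adjusted p = 2.4e-12), AT1G16620 (5.37 ± 0.20, adjusted p = 1.8e-09, 1 of 3 DMSO + salt arrays measured), the iron transporter gene IRT1 (5.25 ± 0.86, adjusted p = 0.00023), AT4G10270 (3.25 ± 0.27, adjusted p = 9.6e-07), AT1G39670 (3.22 ± 0.31, adjusted p = 2.8e-06, 2 of 3) and AT4G10265 (3.15 ± 0.27, adjusted p = 1.2e-06) rose most, with AT3G29120 at least 3.63-fold and the arabinogalactan protein gene FLA20 at least 3.79-fold. MLP328 (-6.08 ± 0.26, adjusted p = 7.9e-09), the marneral synthase gene MRN1 (-5.52 ± 0.27, adjusted p = 1.7e-08), AT2G01422 (-4.39 ± 0.29, adjusted p = 1.6e-07) and AT5G36130 (-4.37 ± 0.23, adjusted p = 2.5e-08) fell most. So did CYP710A4 (at least 20.4-fold), CYP710A3 (at least 12.6-fold), AT4G12170 (at least 7.59-fold) and AT2G28490 (at least 7.07-fold).

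Flavonoid genes rose in 16 and fell in 1 of 22 cases, also adjusted over the list alone (median 0.80, adjusted p = 9.6e-08, and adjusted p = 0.55 with an estimated correlation). TT7 rose by 2.11 ± 0.15 (adjusted p = 2.1e-07), DFR by 1.86 ± 0.12 (adjusted p = 1.3e-07) and LDOX by 1.86 ± 0.12 (adjusted p = 1.7e-07). Xenobiotic genes rose in 13 and fell in 1 of 22 (median 0.54, adjusted p = 0.00015, and adjusted p = 0.55 with an estimated correlation). GSTU24 rose by 2.46 ± 0.13 (adjusted p = 2.8e-08). NRT2.1 rose by 2.52 ± 0.19 (adjusted p = 4.4e-07) and the small heat shock gene HSP23.6 by 2.00 ± 0.22 (adjusted p = 9e-06). VSP1 (-3.77 ± 0.36, adjusted p = 2.7e-06), COR15B (-2.38 ± 0.34, adjusted p = 7.5e-05), ABF1 (-1.55 ± 0.09, adjusted p = 4.8e-08) and LUX (-1.12 ± 0.06, adjusted p = 4.3e-08) fell, and OLEO1 fell at least 8.79-fold.

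Among histone deacetylases 7 rose and 3 fell of 17 (median 0.10), HDA6 by 0.45 ± 0.04 (adjusted p = 3.3e-06) and HDA2 by -0.60 ± 0.10 (adjusted p = 0.0003). Of 24 ion transport genes 6 rose and 4 fell, with a median of -0.09, a mean of 0.00 and a test direction of up. NHX6 rose by 0.70 ± 0.06 (adjusted p = 8.4e-07) and SOS1 by 0.33 ± 0.07, and AKT2 lay between -0.19 and 0.24. In total 15652 features passed, 6959 higher and 8693 lower (44.5% higher, 29.0% under normexp), 2469 at 2-fold (1006 and 1463). All 6 arrays lay on slide 2, so a slide block leaves the estimates as they were and changes only the spread. With slide as a block 15774 passed and both list calls stayed (adjusted p = 2e-07 and 0.00018). On the spread of these 6 arrays alone, 7 of 10 splits of them, the real one included, called as many lists (highest other 9).

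Ky-72 under salt raised AT3G01345 (7.06 ± 0.15, adjusted p = 3.1e-12), AT1G16620 (5.59 ± 0.20, adjusted p = 2.5e-09, 1 of 3 DMSO + salt arrays measured), PR1 (4.60 ± 0.43, adjusted p = 5.2e-06, 1 of 3), the microRNA gene MIR167d (3.41 ± 0.51, adjusted p = 0.00016, 2 of 3), ACD6 (2.94 ± 0.44, adjusted p = 0.00018) and AT3G29120 (at least 4.38-fold). It lowered the acetyltransferase gene NATA1 (-5.73 ± 0.80, adjusted p = 0.00011, 1 of 3 Ky-72 + salt arrays measured), the camalexin synthesis gene CYP71A13 (-4.68 ± 0.87, adjusted p = 0.00081, 1 of 3), AT5G35935 (at least 8.0-fold), AT2G28490 (at least 7.76-fold) and the oleosin gene OLEO1 (at least 9.65-fold). CRU3 (at least 12.8-fold), OLEO2 (at least 10.5-fold) and SESA2 (at least 4.31-fold) fell in the fit without slide and lost their calls with slide as a block (-4.02, -3.21 and -3.75).

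Flavonoid genes rose in 14 and fell in 1 of 22 cases (median 0.42, adjusted p = 1.6e-06, and adjusted p = 0.69 with an estimated correlation). LDOX rose by 1.58 ± 0.12 (adjusted p = 1.2e-06) and UGT75C1 by 1.74 ± 0.14. Seed genes had 0 rises and 7 falls of 14, or 12 falls adjusted over the list alone (median -1.26, adjusted p = 0.024, and adjusted p = 0.78 with an estimated correlation). Clock genes had 4 rises and 13 falls of 24 (median -0.29, adjusted p = 0.043, and adjusted p = 0.32 with an estimated correlation). LUX changed by -0.86 and PRR7 by -0.54, and the clock call was lost under normexp. Xenobiotic genes had 8 rises and 2 falls of 22 (median 0.23, adjusted p = 0.043, and adjusted p = 0.78 with an estimated correlation). GSTU25 rose by 0.73, and the xenobiotic call was lost with slide as a block (median 0.01). NRT2.1 rose by 2.59 ± 0.19 (adjusted p = 7.2e-07), PYL6 by 2.00 ± 0.23 (adjusted p = 2.3e-05) and RBCS2B by 0.90 ± 0.08 (adjusted p = 2.8e-06). COR15B (-2.09 ± 0.34, adjusted p = 0.0003), VSP1 (-2.86 ± 0.36, adjusted p = 4.4e-05) and MBF1C (-0.85 ± 0.09, adjusted p = 8.4e-06) fell.

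For histone deacetylases the counts were 6 rises and 3 falls of 17, with HDA2 at -0.58 ± 0.10 and HDT1 at 0.29. The test passed 13510 features, 6177 higher and 7333 lower (45.7% higher, 27.2% under normexp, 51.0% under quantile normalization, 51.3% in the value table), and 1719 at 2-fold (769 and 950). Among features with a locus 5058 were higher and 4980 lower, at 2-fold 470 and 371. DMSO + salt lay on slide 2 and Ky-72 + salt on slide 3, linked through Ky-72 replicate 1 on slide 2, and with slide as a fixed block 4633 features passed. In that fit the list values were flavonoid 0.50 (adjusted p = 7.7e-07), seed -0.95 (0.046), clock -0.26 (0.026) and, as an added call, heat shock -0.73 (0.011, against -0.47 and 0.09 without slide). A random slide block gave 12625 features.

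Under salt, Ky-9 exceeded Ky-72 in AT4G10270 (3.65 ± 0.27, adjusted p = 4.2e-06) and AT4G10265 (3.29 ± 0.27, adjusted p = 5.4e-06), and was lower in CYP710A4 (at least 10.9-fold), CYP710A3 (at least 10.1-fold), AT5G36130 (-3.39 ± 0.23, adjusted p = 2.4e-06), AT1G23160 (-3.41 ± 0.29, adjusted p = 7.9e-06, 1 of 3 Ky-9 + salt arrays measured) and MRN1 (-3.27 ± 0.27, adjusted p = 5.4e-06). Heat shock genes were higher in 8 and lower in 0 of 19 (median 0.94, adjusted p = 4.7e-06, and adjusted p = 0.32 with an estimated correlation; slide as a block 1.11, adjusted p = 4.8e-09), HSP90.1 by 1.17 ± 0.11 (adjusted p = 1e-05) and ROF2 by 1.04 ± 0.10 (adjusted p = 2e-05). Flavonoid genes were higher in 11 and lower in 2 of 22, or 12 and 3 adjusted over the list alone (median 0.27, adjusted p = 0.0014, and adjusted p = 0.76 with an estimated correlation). They lost the call with slide as a block (0.32, adjusted p = 0.082). Xenobiotic genes were higher in 6 and lower in 0 of 22 (median 0.29, adjusted p = 0.01, and adjusted p = 0.76 with an estimated correlation; slide as a block 0.41, adjusted p = 0.00088), DTX1 by 1.38 ± 0.20.

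PR5 (-1.29 ± 0.23), the repeat-silenced SDC (-1.42 ± 0.15, adjusted p = 3.2e-05) and ABF1 (-1.02 ± 0.09, adjusted p = 7.9e-06) were lower with Ky-9. PR1 was lower (-2.71 ± 0.43, adjusted p = 0.00071) in the fit without slide and lost its call with slide as a block (-1.90). No difference passed for HDA9 (0.00, adjusted p = 0.97), SOS1 (0.02), AVP1 (-0.01) or AKT2 (0.06). In all 6630 features differed, 3091 higher and 3539 lower, 715 at 2-fold (252 and 463), against 1025 with slide as a fixed block, 3841 with the spread of both groups alone and 5847 with slide as a random block.

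Under salt the effects of both compounds correlated across genes at r = 0.759 (rho 0.747, covariance 0.238), against 0.5 and 0.0242 in simulated unchanged groups with the same shared controls, a difference in covariance of 0.214. The sign was the same in 79.6% against 66.7%. Both raised 4288 features against 1355 for independence and lowered 5483 against 2009, while 214 went opposite ways. Between conditions, where no arrays are shared, the Ky-9 effects without and with salt correlated at 0.326 and the Ky-72 effects at 0.636. Ky-9 raised 3134 features in both conditions against 1669 for independence and lowered 3478 against 2053, and Ky-72 raised 3734 against 1274 and lowered 4616 against 1705. Slide 3 held 2 of the Ky-72 and all 3 of the Ky-72 + salt arrays, and no DMSO array of either condition. A shift of slide 3 could raise the Ky-72 agreement, while each Ky-9 effect lies within a slide. The values of the compounds are therefore not directly comparable.

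Whether salt altered each compound's effect was tested as an interaction. For Ky-9, large negative terms were found in AT2G17850 (-9.34 ± 0.51, adjusted p = 4.4e-08), AT2G29870 (-7.23 ± 0.82, adjusted p = 2.4e-05), AT2G14247 (-6.31 ± 0.40, adjusted p = 1.5e-07) and AT5G10040 (-6.30 ± 0.73, adjusted p = 2.8e-05, 2 of 3 DMSO + salt arrays measured), all raised by Ky-9 without salt. SRO4 had a negative term too (adjusted p = 7.6e-07), of undetermined size, as 0 of 3 arrays of either salt group were well above background. Large positive terms were found in AT4G33720 (4.55 ± 0.69) and CIPK20 (4.30 ± 0.24, adjusted p = 5.3e-08). Those of AT2G37030 (adjusted p = 0.0021), AT4G27654 (adjusted p = 0.00054) and AT1G49210 (adjusted p = 1.7e-05) were positive, of undetermined size. AT2G37030 was well above background on 0 of 3 DMSO + salt and 1 of 3 Ky-9 arrays, AT4G27654 on 0 of 3 Ky-9 arrays, and AT1G49210 on 0 of 3 arrays of both groups.

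HSP70 (-3.72 ± 0.22, adjusted p = 7e-08), HSP90.1 (-3.32 ± 0.15, adjusted p = 8.9e-09) and GSTU25 (-1.45 ± 0.13, adjusted p = 2.2e-06) also had negative terms with Ky-9. CYP707A2 (4.01 ± 0.18, adjusted p = 1.1e-08), ZAT10 (3.99 ± 0.59, adjusted p = 0.00019) and AKT2 (1.81 ± 0.14, adjusted p = 9.7e-07) had positive ones. SOS1 lay between -0.22 and 0.20. Rapid factors had 10 positive and 0 negative terms of 25 (median 1.21, adjusted p = 0.0099, and adjusted p = 0.67 with an estimated correlation; slide as a block 0.012). Another 5 lists passed just under the threshold (adjusted p = 0.05 each, and adjusted p = 0.67 with an estimated correlation): photosynthesis (9 and 1 of 22, median 0.20), heat shock (2 and 7 of 19, -0.50), xenobiotic (0 and 8 of 22, -0.32), reference (0 and 4 of 8, -0.25) and abscisic acid genes (11 and 2 of 32, median 0.20, or -0.00 under normexp). These 5 calls were lost with slide as a block (adjusted p = 0.06 each). Both Ky-9 differences in this term lie within a slide, so the block leaves the estimate as it was and changes only the spread. The loss reflects calls at the threshold and not an effect of slide. The interaction passed for 12315 features, 5475 positive and 6840 negative (44.5% positive, 24.7% under normexp, 52.3% under quantile normalization, 52.1% in the value table), for 12420 with slide as a fixed block, and for 18578 under normexp.

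For Ky-72 and salt, large negative terms were found in AT2G17850 (-5.84 ± 0.51, adjusted p = 3e-05) and AT2G29870 (-5.22 ± 0.82, adjusted p = 0.002). SAG13 (adjusted p = 0.0015) and SRO4 (adjusted p = 0.0011) had negative terms of undetermined size, with SAG13 well above background on 0 of 3 DMSO and 0 of 3 Ky-72 + salt arrays and SRO4 on 0 of 3 arrays of either salt group. Large positive terms were found in SOB5 (3.57 ± 0.67, adjusted p = 0.0061, 2 of 3 DMSO + salt arrays measured), the dormancy gene DOG1 (3.24 ± 0.37, adjusted p = 0.00024, 1 of 3) and IAA5 (3.18 ± 0.60, adjusted p = 0.0062, 2 of 3 Ky-72 arrays measured). Heat shock genes had 0 positive and 7 negative terms of 19, or 1 and 7 adjusted over the list alone (median -0.47, adjusted p = 3.9e-05, and adjusted p = 0.21 with an estimated correlation). HSP90.1 was at -1.91 ± 0.15 (adjusted p = 1.1e-05). Auxin genes had 6 positive and 1 negative of 25, or 10 and 1 adjusted over the list alone (median 0.49, adjusted p = 3.9e-05, and adjusted p = 0.21 with an estimated correlation). SAUR-AC1 was at 2.2 ± 0.25 (adjusted p = 0.00021). Xenobiotic genes had 0 and 3 of 22 (median -0.44, adjusted p = 0.00029, and adjusted p = 0.24 with an estimated correlation). GSTU25 was at -1.45 ± 0.13 (adjusted p = 3e-05).

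Cell cycle genes had 2 positive and 1 negative term of 29, or 6 and 1 adjusted over the list alone (median 0.15, adjusted p = 0.0011, and adjusted p = 0.33 with an estimated correlation). Clock genes had 0 and 6 of 24, or 2 and 6 adjusted over the list alone (median -0.15, adjusted p = 0.017, and adjusted p = 0.21 with an estimated correlation). Flavonoid genes had 2 and 4 of 22, or 2 and 8 adjusted over the list alone (median -0.35, adjusted p = 0.029, and adjusted p = 0.66 with an estimated correlation). UGT78D2 was at -0.90. The interaction passed for 2287 features, 1095 positive and 1192 negative (47.9% positive, 13.8% under normexp, 53.5% under quantile normalization, 57.0% in the value table). It passed for 1334 on the spread of these 4 groups alone, 9898 under normexp and 7959 without the filter on dim probes. Slide and group cannot be told apart for this term, and with slide as a random block 1864 features passed and the 6 list calls stayed.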

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

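The low-oxygen tests, the iron tests and the standard-error test were chosen after the result was seen, and the other splits of the arrays and the correlation with the slide shift before.

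The results of this paragraph came up because a compound's effect differed between no salt and salt by a test of the difference itself. For Ky-9 this held for 12315 features. The terms named were AT2G37030 5.54, AT4G27654 5.28, AT1G49210 5.00, AT4G33720 4.55, CIPK20 4.30, AT2G17850 -9.34, SRO4 -8.63, AT2G29870 -7.23, AT2G14247 -6.31 and AT5G10040 -6.30. The sizes for AT2G37030, AT4G27654, AT1G49210 and SRO4 are not determined, as at least 1 of the 4 groups had 0 of 3 arrays well above background. The lists were rapid stress transcription factors (median 1.21), abscisic acid genes (0.20, or -0.00 under normexp), photosynthesis (0.20), heat shock (-0.50), xenobiotic detoxification (-0.32) and reference genes (-0.25). For Ky-72 it held for 2287 features. The terms named were AT1G33760 3.75, SOB5 3.57, DOG1 3.24, AT1G18486 3.22 (-0.15 under normexp), IAA5 3.18, AT2G17850 -5.84, AT2G29870 -5.22, SAG13 -4.64, SRO4 -4.54 and CYP71A13 -4.45. For the same reason the sizes for AT1G18486, SAG13, SRO4 and CYP71A13 are not determined. The lists were circadian clock (-0.15), heat shock (-0.47), cell cycle (0.15), auxin (0.49), flavonoid (-0.35) and xenobiotic genes (-0.44). The calls of AT1G33760 and CYP71A13 each ended when any of several single arrays was left out, and with slide or replicate number as a block.

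Other splits of the same arrays were counted with the spread of the compared groups alone. For the 9 simple comparisons there are 10 splits, too few for a share under 0.05. The real genes called were 14561 (Ky-9), 10489 (Ky-72), 12799 (Ky-9 against Ky-72), 13481, 19383 and 12228 (salt in DMSO, Ky-9 and Ky-72), 13426 and 10609 (Ky-9 and Ky-72 under salt) and 3842 (Ky-9 against Ky-72 under salt). In each, the real split was the 1 with as many, and the highest other called 0. Lists called, with the highest other split and the number of splits with as many, were in the same order 7, 8 and 3; 4, 4 and 4; 3, 5 and 6; 10, 9 and 1; 7, 10 and 6; 8, 7 and 1; 2, 9 and 7; 1, 7 and 10; 3, 10 and 9. Only for salt in DMSO and salt in Ky-72 was the real split the 1 with as many. Elsewhere, and most under salt, other splits called as many lists, so those numbers of list calls do not stand out. For the interactions 100 splits were drawn. For Ky-9 12035 genes were called, 2 splits had as many and the highest other called 17235. For Ky-72 1334 were called, 4 splits had as many and the highest other called 16926. The latter, several times the real count, points to a structure of the samples: that split keeps the labels without salt and turns them under salt, so that it adds both compound effects. The highest split for Ky-9 is of the same kind. The lists called in the interactions were 1 for Ky-9 (90 splits with as many, highest 11) and 6 for Ky-72 (29 splits, highest 9), so other splits of the arrays often called as many lists.

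Genes known to respond to low oxygen were higher with both compounds without salt. They were gathered after the values were seen, so they are not independent evidence of their direction or of its change with salt. Of 46 measured, 43 rose and 2 fell with Ky-9 (median 2.58, adjusted p = 2e-23, and adjusted p = 0.063 with an estimated correlation) and 39 rose and 0 fell with Ky-72 (median 1.57, adjusted p = 1.1e-18, and adjusted p = 0.17 with an estimated correlation). Over 5 ways of scaling the signal these medians ran from 2.16 to 2.58 with Ky-9 and from 1.40 to 1.57 with Ky-72. A slide effect is excluded for Ky-9, as the 2.58 was measured within slide 1, and stays open for Ky-72 (slide 3 minus slide 2 within Ky-72 0.15). Within the limit of a list gathered afterwards, the values argue against its rise as a whole whatever the salt condition. The larger absolute median under salt was 0.23. Single members are not covered, as with Ky-9 10 rose and 12 fell under salt. For Ky-72 the slides compared differ between the conditions, so slide and a change with salt cannot be told apart. The medians under salt, -0.02 with Ky-9 and -0.23 with Ky-72, lay below those without salt (2.58 and 1.57) by more than the standard deviation of the members (1.09 and 0.67). Air supply or handling that differed between groups could not be excluded: the largest standard deviation of the list mean between arrays of a group without salt was 0.25, against group means of 0.00, 2.73 and 1.61 for DMSO, Ky-9 and Ky-72.

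Iron deficiency genes, gathered in the same way, were higher with Ky-9 in both conditions: 15 rose and 0 fell of 19 without salt (median 1.27, adjusted p = 6e-09, and adjusted p = 0.027 with an estimated correlation), and 11 rose and 2 fell under salt (median 0.42, adjusted p = 0.013, and adjusted p = 0.41 with an estimated correlation). Over 5 ways of scaling the signal the medians ran from 1.03 to 1.27 without salt and from 0.17 to 0.42 under salt. A slide effect is excluded, as both groups lay on 1 slide in each condition: the 1.27 was measured within slide 1, and under salt the lowest Ky-9 array had a list mean 0.53 above the highest DMSO array within slide 2. A larger share of root tissue stays open. The 14 root-abundant members without IRT1 had a median of 0.54 without salt (11 higher, 0 lower) and -0.06 under salt, where 3 were higher and 4 lower with a standard deviation of 0.79. Members that go both ways decide nothing.

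Fewer features passed between the salt groups on slides 2 and 3 once slide was a term (4633 against 13510 for Ky-72 under salt). The 13510 features had a median absolute log2 fold change of 0.45 (median standard error 0.09) without the term and 0.43 (0.16) with it, a median of 0.99 of their size was kept and 98.5% kept their direction. As these features were chosen by passing without the term, keeping their direction was favoured. The estimates with and without the term correlated at 0.824. A shift between the slides as the source of most calls stays open. Across genes, which are not independent replicates, slide 3 minus slide 2 within Ky-72 correlated with the Ky-72 effect under salt at 0.065 (0.081 among those called), under the bound of 0.1 set beforehand. The low correlation argues against such a shift, but that bound overlooked the design: the slide difference and the slide term both rest on the 1 Ky-72 array of slide 2. The standard error was wider with the slide term, with a median ratio of 1.82 between the fits. The layout of the arrays widens it whatever the data, as 1 array links the slides. That ratio could hardly have come out otherwise and is no separate evidence on the cause.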

How the results depend on the processing

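Leaving out arrays for the agreement of both compounds was chosen after the result was seen, and the other alternatives before. The 2-fold threshold admits fewer features by construction and moved all 11 counts. Under every other alternative 7 of the 11 stayed within 1.5 times, and of the other 4 only the drop for Ky-72 under salt was tested for its cause. With the threshold the counts were 2630, 1939 and 2396 (Ky-9, Ky-72, Ky-9 against Ky-72), 3376, 5618 and 3165 (salt in DMSO, Ky-9, Ky-72), 2469, 1719 and 715 (the first 3 under salt) and 3325 and 500 (interactions of Ky-9 and Ky-72 with salt). Slide as a fixed block gave 4633 for Ky-72 under salt and 1025 for Ky-9 against Ky-72 under salt, and the spread of the compared groups alone 3841 for the latter and 1334 for the Ky-72 interaction. Normexp gave 18578 and 9898 for the interactions of Ky-9 and Ky-72, and no filter on dim probes 7959 for the latter. Of 209 list tests 63 were called, 1 with an estimated correlation, 125 with fry, 61 with quantile normalization, 69 with normexp and 64 with the value table. The agreement of both compounds (0.557) was 0.625 under normexp and 0.581 in the value table, and under salt (0.759) 0.8 under normexp.

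Signs turned under normexp for HAK5 (0.05 with Ky-9, 0.05 with Ky-72, -0.62 in the Ky-9 interaction), HDA18 (-0.01 for salt in Ky-9, -0.32 for Ky-72 under salt, -0.05 in the Ky-72 interaction), AP3 (-0.09 for Ky-72 under salt), SEP1 (-0.53 and -0.42 in the interactions of Ky-9 and Ky-72), EDS1 (-0.38 and -0.52), MCM5 (-0.13, Ky-9) and AT1G18486 (-0.15, Ky-72). In the value table they turned for YLS8 (-0.02 with Ky-9), LHCB4.2 (-0.01 for Ky-9 against Ky-72 under salt) and, for salt in Ky-72, YLS8 (0.07) and RBCS1B (0.05). For salt in Ky-72 quantile normalization turned AHA1 (0.12) and YLS8 (0.05), and with normexp AHA1 was 0.15, RBCS1B 0.07 and YLS8 0.08. Slide as a fixed block turned HDA10 (-0.43 for Ky-72 under salt, 0.49 for Ky-9 against Ky-72 under salt) and NHX4 (0.03 in the latter). The cause was not tested.

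Leaving out each array in turn gave 13097 to 13729 (Ky-9), 11176 to 13421 (Ky-72), 12319 to 13110 (Ky-9 against Ky-72), 13802 to 14667, 18347 to 19074 and 12564 to 14587 (salt in DMSO, Ky-9, Ky-72), 13421 to 14404, 11414 to 12037 and 4924 to 5297 (the first 3 under salt) and 10629 to 11561 and 1674 to 2025 (interactions). The agreement ran from 0.538 to 0.579, and under salt from 0.738 to 0.774.

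With replicate number as a block the counts were, in the same order, 15097, 13879, 14426, 15625, 20099, 15290, 15637, 13480, 6652, 12234 and 2256. Replicate numbers did not pair the samples: residuals of equal number correlated at -0.23 to 0.27 and 0 comparisons had every pair over 0.1. The 2 rule-based lists and fixed slide blocks for 5 comparisons were not run. Between 55.6% and 62.7% of spots on an array were well above background, and features dim in every group were not judged.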

Other observations

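The lists of low-oxygen and iron genes, and every test on them, were chosen after the values were seen.

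Without salt the fermentation gene PDC1 rose by 4.67 ± 0.18 with Ky-9 (adjusted p = 3e-10) and 2.50 ± 0.18 with Ky-72 (adjusted p = 3.9e-07), and the alcohol dehydrogenase gene ADH1 by 1.59 ± 0.12 (adjusted p = 1.2e-07) and 1.11 ± 0.12 (adjusted p = 8.6e-06), n = 3 arrays per group. The regulator genes HRE2 (5.42 ± 0.35 and 2.31 ± 0.35) and HRA1 (3.80 ± 0.26 and 3.18 ± 0.26) and the cysteine oxidase gene PCO1 (4.11 with Ky-9 and 1.97 with Ky-72) rose as well. Ky-9 exceeded Ky-72 in 36 of 46 low-oxygen genes and was lower in 1 (median 1.01, adjusted p = 7.1e-11, and adjusted p = 0.38 with an estimated correlation). Slide and compound cannot be told apart in that comparison. Under salt 10 low-oxygen genes rose and 12 fell with Ky-9 (mean 0.06, adjusted p = 0.92, and adjusted p = 0.98 with an estimated correlation), and 2 rose and 16 fell with Ky-72 (mean -0.38, adjusted p = 0.045, and adjusted p = 0.88 with an estimated correlation). Ky-9 exceeded Ky-72 under salt in 12 and was lower in 2 (median 0.16, adjusted p = 0.0011, and adjusted p = 0.64 with an estimated correlation). These 2 groups lay on different slides. PDC1 under salt was below DMSO with Ky-9 (-1.58 ± 0.18, adjusted p = 1.2e-05) and Ky-72 (-1.65 ± 0.18, adjusted p = 1.4e-05). The interaction with salt was negative for 38 of 46 genes and positive for 1 with Ky-9 (median -2.23, adjusted p = 9.1e-21, and adjusted p = 0.1 with an estimated correlation), and negative for 39 and positive for 0 with Ky-72 (median -1.93, adjusted p = 1.3e-42, and adjusted p = 0.015 with an estimated correlation). Mean levels per group relative to DMSO were 0.00 (SD between arrays 0.25) for DMSO, 2.73 (0.04) for Ky-9, 1.61 (0.24) for Ky-72, -0.38 (0.19) for DMSO + salt, -0.31 (0.08) for Ky-9 + salt and -0.76 (0.12) for Ky-72 + salt.

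Among iron deficiency genes the transcription factor genes bHLH101 (5.32 ± 0.29, adjusted p = 7.8e-09), bHLH38 (4.07 ± 0.59, adjusted p = 6.6e-05) and bHLH39 (3.51 ± 0.28, adjusted p = 2.6e-07) and the peptide genes IMA3 (3.15 ± 0.17, adjusted p = 8.4e-09) and IMA1 (2.45 ± 0.13, adjusted p = 8e-09) rose with Ky-9 without salt. With Ky-72 12 of 19 rose and 1 fell (median 0.50, adjusted p = 0.00032, and adjusted p = 0.17 with an estimated correlation), bHLH101 by 2.65 ± 0.29 (adjusted p = 1.2e-05), while bHLH38 was at 0.66 ± 0.59 (adjusted p = 0.39). Under salt with Ky-9 bHLH38 rose by 2.63 ± 0.59 (adjusted p = 0.0023) and bHLH39 by 1.94 ± 0.28 (adjusted p = 8.2e-05), but PYE (-0.24 ± 0.07) and IRT2 (-0.54 ± 0.12) fell. Group means were 0.00 for DMSO, 1.83 for Ky-9, 0.71 for Ky-72, -0.04 for DMSO + salt, 0.81 for Ky-9 + salt and 0.21 for Ky-72 + salt.

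One hypothesis is that the low-oxygen genes follow the oxygen supply of seedlings in liquid medium rather than a direct action of the compounds that holds in any condition. For the list as a whole, gathered after the values were seen, the values argue against the latter. The larger absolute list median under salt was 0.23, against 2.58 and 1.57 without salt. The standard deviation between members was 1.09 (Ky-9) and 0.67 (Ky-72), and for Ky-72 the slides compared differed between the conditions. An action of the compounds that depends on the salt condition, or on the 2 h that passed, was not tested and stays open. The oxygen supply was not settled either. The spread between arrays of a group without salt (0.25) is small beside the group means. Nothing in the labels, however, separates the supply of air from the group, or says why compound and DMSO groups without salt would differ in it. A second hypothesis, that the iron genes of Ky-9 samples reflect more root tissue, stayed open: the root-abundant list without IRT1 had a median of 0.54 without salt (11 of 14 higher, 0 lower) and -0.06 under salt, where 3 were higher and 4 lower. Measuring the low-oxygen genes after aerated culture, and after 2 h without salt, would test the first directly, and measuring the iron genes in roots and shoots sampled apart would test the second.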
